A study of Mus musculus with 30 samples.

How the data were processed

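Gene expression was measured in tumours of EL4 cells, a mouse T cell lymphoma line, grown under the skin of mice that had or had not received an antibiotic cocktail and were then given oxaliplatin, a platinum drug that damages DNA. Each of 30 samples was hybridised to 1 Affymetrix mouse gene array, and the samples form 6 groups of 5: water or antibiotics, at 0, 6 or 18 h after the drug. Groups and times were taken from the sample labels. The labels number the samples but do not state that each came from a separate mouse, so the p-values measure the spread between these samples, part of which may be technical. The sample numbers run through the whole series in blocks by group and pair no samples between groups. If the samples were handled in that order, its effect could not be told apart from that of the group.

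The deposited values are on a log2 scale, with 28853 rows per array. The submitters' processing notes name Partek 6.6 without saying what it was used for. How the probes were summarised and normalised is not given in the sources used here. Array medians over all rows lay between 7.253 and 7.365, and the sorted values of the arrays differed by up to 0.276, so the arrays had not been given identical distributions. Values were used as deposited. The number of arrays limits the precision, and the median residual SD of a gene was 0.115 on the log2 scale.

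Row names were matched to genes through the platform's probe-to-gene table, which can be old. Of 23353 rows listed there, 21775 had 1 gene symbol and 1578 had several, and 5500 rows of the deposited table had no symbol here. Rows with 1 symbol were looked up in the mouse reference by Entrez number, which found 21684 and updated 0 symbols. For the 998 genes with more than 1 row the row with the highest mean was used, which gave 19938 genes. Coordinates are not given because no genome build is named for the array.

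One linear model with 6 group means was fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 24 residual degrees of freedom and 3.63 prior degrees of freedom. The 10 comparisons were antibiotics against water at 0, 6 and 18 h and averaged over the times, 6 h and 18 h against 0 h within water and within antibiotic mice, and the interaction of antibiotics with time at 6 h and at 18 h. P-values were adjusted within each comparison by the Benjamini-Hochberg method, all tests were two-sided, and a gene passed at an adjusted p under 0.05. About 997 genes would have an unadjusted p under 0.05 by chance. Errors of log2 fold changes are the SEs of the model. The script was tested on simulated data for antibiotics against water at 18 h with 200 of 19938 genes changed and independent noise for each gene. It recovered 88% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1, with 9 false calls (4.57% of calls) and 0 wrong signs. Genes that vary together were not simulated, so the share of false calls may differ on the real arrays.

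Gene lists were written before the data were examined, as were the comparisons, the rule for named genes and most of the other settings tried. The 32 lists cover p53 targets, mitosis, DNA replication, DNA repair, ribosome biogenesis, unfolded protein and integrated stress, heat shock, immediate early genes, hypoxia and glycolysis, inflammatory cytokines and NF-kB targets, reactive oxygen production, antioxidant defence, type I interferon response, interferon gamma response with MHC class I, MHC class II presentation, phagocytosis with Fc receptors and complement, circadian clock and glucocorticoid response. They also hold markers of monocytes and macrophages, alternatively activated macrophages, neutrophils, dendritic cells, NK and cytotoxic cells, T cells, B and plasma cells, mast cells and eosinophils, endothelium, fibroblasts and matrix, skeletal muscle, keratinocytes, adipocytes, and erythroid cells and platelets. Of 538 planned members 502 were tested, and the others, among them Cdkn1a, were on rows with several symbols or on no named row and were not analysed here. EL4 cells are T cells, so the T cell list does not separate tumour from host.

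The planned list test was camera with a preset correlation of 0.01, adjusted over the 32 lists. Random regroupings of the arrays called a median of 8 to 12 lists by this test, so its calls alone were given little weight. Beside it stand camera with an estimated correlation, fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, and limma on the mean of each list per array, the last chosen after the data were seen. Differences in list means between 2 groups were also given an exact permutation test, likewise chosen later, whose adjusted p over the 32 lists can pass only where several lists reach the smallest p. For every list that camera called, the median, the mean and the test had the same sign. List means per array are averages of log2 values relative to each gene's mean over the 30 arrays. On simulated data for antibiotics against water at 18 h, with 1 of the 32 lists shifted by 0.2, camera with the preset correlation and limma on list means called that list and 0 others. The simulated noise was independent between genes. The 0 false calls therefore do not show how the tests behave where genes of a list vary together.

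Named genes were those with the 8 largest and 8 smallest log2 fold changes among genes that passed, up to 2 passing members per list with the largest change, and fixed genes. The fixed genes were Tnf, Il1b, Cybb, Nos2, Ncf1 and Sod2 for antibiotics against water and for interactions, and Mdm2, Tnf, Cybb, Nos2 and Dbp for time, to which Cdkn1a would have belonged. Where 0 genes passed, the 5 with the smallest p in each direction could be named. The text names some of these and not always in order of size (Gbp5, Usp18 and Prrg4 are among those passed over), so which of them appear was chosen after their values were seen, and placeholder symbols were left out.

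Alternatives were quantile normalisation, subtraction of array medians, leaving out the dimmest 40% of genes, all rows of each gene, fits of only the groups compared, eBayes with trend and robust options, an ordinary linear model, array weights, skin and muscle list means as covariates, a minimum change of 1.5-fold, and leaving out each array. Others chosen after seeing the data were the interquartile range of each array as a covariate and leaving out arrays that stood apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.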

Results

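The series asked how treating mice with antibiotics before chemotherapy affects the response of a tumour to oxaliplatin. EL4 lymphoma cells were injected under the skin of mice that had been given an antibiotic cocktail or water, and tumours were taken at 0, 6 or 18 h after oxaliplatin. Each of the 6 groups held 5 arrays, and values are log2 expression as deposited. The samples hold no tumours without oxaliplatin at 6 or 18 h. An effect of the drug therefore cannot be separated from other change with time, and a response below means a change from 0 h. The spread between arrays was not equal in all groups: the median SD of a gene was 0.0799 in water mice at 6 h and 0.135 in antibiotic mice at 6 h, and the other groups lay between 0.0954 and 0.111. One shared error was used for all groups, so it understates the spread of the antibiotic group at 6 h.

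Markers of tissue around the tumour differed between single arrays. The keratinocyte list mean was 2.14 on water 6 h array 1 and 1.94 on antibiotic 6 h array 1, relative to the mean of all arrays, and the skeletal muscle list mean was 1.56 on antibiotic 6 h array 5. Neither list was called by limma on list means in any of the 10 comparisons, and camera's calls of them did not hold with an estimated correlation. For antibiotics against water over all times the mean differences were 0.060 ± 0.205 (SE) for keratinocyte and 0.0040 ± 0.175 (SE) for muscle markers. Errors of this size leave room for an uneven share of skin or muscle between groups. From 0 to 6 h in antibiotic mice the keratinocyte list mean rose by 0.711 (exact permutation p = 0.024, 0.38 adjusted over the 32 lists). Antibiotic 6 h arrays 2, 3 and 4 (0.231, -0.052 and 0.449) also lay above the highest antibiotic 0 h array (-0.136). Array 5 (-0.213) did not.

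**Figure D1:**
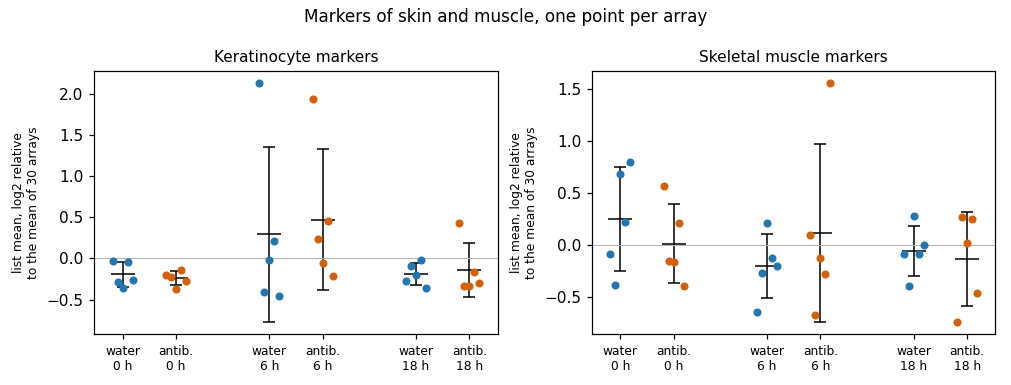
Mean of the keratinocyte list (left) and the skeletal muscle list (right) on each array, as log2 relative to the mean of the 30 arrays; points are arrays, horizontal marks are group means and bars are SD (n = 5). Keratinocyte means of 2.14 and 1.94 stand out at 6 h, as does a muscle mean of 1.56 in an antibiotic tumour.

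In water mice, genes known to be induced by p53, the transcription factor that responds to DNA damage, rose within 6 h of oxaliplatin. Of 27 list members 11 rose and 0 fell. Trp53inp1, a p53-induced regulator of cell death, rose by 1.34 ± 0.18 (SE) on the log2 scale, Fas, a death receptor, by 0.80 ± 0.15, and Mdm2, the ligase that degrades p53, by 0.58 ± 0.076. Ddias rose by 1.08 ± 0.17, and Cd80, a costimulatory ligand, by 0.96 ± 0.17. Some genes of mitosis went the other way, with 6 of 23 lower (9 adjusted over the list alone) and 0 higher, among them the kinases Aurka (-0.36 ± 0.056) and Plk1 (-0.35 ± 0.049). For this list the adjusted p was 0.33 with an estimated correlation. Fos, an immediate early transcription factor, rose by 0.88 ± 0.15, and it was the 1 of 14 members of its list to pass (3 adjusted over the list alone; adjusted p = 0.57 for the list with an estimated correlation). The histone genes H2ac4 (-0.53 ± 0.12) and H4c3 (-0.40 ± 0.090) were lower, but such genes have near-identical copies that an array may not separate. Tnf (-0.020 ± 0.064), Cybb (-0.12 ± 0.23), Nos2 (-0.13 ± 0.29) and Dbp (0.15 ± 0.061) did not pass.

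In all, 222 genes passed between 0 and 6 h in water mice, 139 higher and 83 lower. The p53 list was called by camera with an adjusted p of 8.92e-22 and an adjusted p of 0.00166 with an estimated correlation, and 15 members rose when adjusted over the list alone. The test of list means by limma also called mitosis (adjusted p = 0.0357) and unfolded protein and integrated stress (adjusted p = 0.0357; 0.30 as an adjusted p with an estimated correlation), where only Herpud1 (-0.30 ± 0.065) passed of 15 members and 2 when adjusted over the list alone. In the exact permutation test of list means the p53, mitosis and integrated stress lists had adjusted p-values of 0.17, 0.17 and 0.18. The count fell to 131 without water 0 h array 2 and to 119, 126, 136 and 132 without water 6 h arrays 1, 3, 4 and 5.

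By 18 h the change from 0 h in water mice had widened to 2816 genes, 1233 higher and 1583 lower. In the p53 list 19 of 27 members were higher (22 adjusted over the list alone) and 0 lower, with Trp53inp1 at 1.55 ± 0.18, Fas at 1.15 ± 0.15 and Mdm2 at 0.65 ± 0.076. In ribosome biogenesis 17 of 26 members fell (19 adjusted over the list alone) and 0 rose, including Nop58 (-0.33 ± 0.058) and Rrp9 (-0.28 ± 0.049), which act in ribosomal RNA processing, but the list's adjusted p was 0.31 with an estimated correlation. Genes of the integrated stress response, which cells use when amino acids or protein folding are limiting, fell in 6 of 15 cases (7 adjusted over the list alone), led by Chac1 (-1.20 ± 0.17) and Trib3 (-0.64 ± 0.15), with an adjusted p of 0.28 with an estimated correlation. The amino acid transporters Slc1a4 (-0.98 ± 0.097) and Slc6a9 (-0.96 ± 0.13) were lower as well.

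Some genes of DNA replication and mitosis were lower in water tumours at 18 h, and the adjusted p of the lists was 0.38 and 0.42 with an estimated correlation. In DNA replication 8 of 25 members fell, among them the origin licensing genes Orc1 (-0.31 ± 0.059) and Cdc6 (-0.30 ± 0.062). In mitosis 7 of 23 fell, with Cenpf at -0.32 ± 0.068, and in DNA repair 4 of 20 fell, with the checkpoint kinase Chek1 at -0.37 ± 0.071 (the repair list was not called by list means, adjusted p = 0.117, and its adjusted p was 0.51 with an estimated correlation). Heat shock genes fell in 4 of 9 cases, led by the chaperone Hsph1 (-0.39 ± 0.061; adjusted p = 0.31 with an estimated correlation). Adjusted over the list alone the numbers were 9, 10, 4 and 4 for replication, mitosis, repair and heat shock. Histone genes were again among the lowest values (H2ac4 -1.20 ± 0.12, H2bc3 -0.92 ± 0.094, with the same limit on near-identical copies).

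Some inflammatory, interferon and stromal genes rose at 18 h in water mice. Of 24 inflammatory and NF-kB target genes 6 rose, including the cytokines Il1b (1.13 ± 0.24) and Il6 (0.97 ± 0.31), and Tnf rose by 0.23 ± 0.064 (adjusted p = 0.31 for the list with an estimated correlation). In the reactive oxygen list 2 of 12 rose, Cyba (0.31 ± 0.055) and Ncf4 (0.26 ± 0.062), which encode subunits of the phagocyte NADPH oxidase, while Cybb (0.37 ± 0.23) and Nos2 (0.15 ± 0.29) did not pass, and the list's adjusted p was 0.28 with an estimated correlation. Interferon gamma and MHC class I genes rose in 6 of 15 cases, with the checkpoint ligand Cd274 at 0.51 ± 0.13, and type I interferon genes in 4 of 21, with Bst2 at 0.47 ± 0.046, where the adjusted p of the lists was 0.38 and 0.46 with an estimated correlation. Endothelial markers rose in 6 of 16 cases (Eng 0.33 ± 0.11), fibroblast and matrix markers in 6 of 18 (Mmp2 0.78 ± 0.15), and mast cell and eosinophil markers in 3 of 11 (Fcer1a 0.42 ± 0.10), each with an adjusted p of 0.38 with an estimated correlation. Among macrophage markers 3 of 12 rose, including Mpeg1 (0.64 ± 0.19), and 3 of 22 phagocytosis genes, including Cd36 (0.76 ± 0.19), and list means called neither list (adjusted p = 0.238 and 0.12; 0.53 each as an adjusted p with an estimated correlation). Immediate early genes rose in 5 of 14 cases and fell in 1 (adjusted p = 0.50 for the list with an estimated correlation). Adjusted over the list alone the numbers higher were 9 for inflammatory, 3 for reactive oxygen, 10 for interferon gamma, 7 for type I interferon, 8 for endothelial, 12 for fibroblast, 3 each for mast cell, macrophage and phagocytosis and 5 for immediate early genes.

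In other lists few or no members passed in water tumours at 18 h. Passing members numbered 0 of 17 for neutrophil, 0 of 9 for dendritic, 0 of 14 for NK and cytotoxic cell, 0 of 17 for skeletal muscle and 0 of 12 for keratinocyte markers. Their list means changed from 0 h by 0.16 ± 0.0997 (SE), 0.013 ± 0.059, 0.24 ± 0.10, -0.30 ± 0.302 and 0.0054 ± 0.354, and limma on list means called none of these 5. They numbered 1 of 10 for alternatively activated macrophages (Chil3, 1.59 ± 0.31), 1 of 10 for B and plasma cells (Cd79b, 0.50 ± 0.071), 1 of 10 for adipocytes (Fabp4, 0.58 ± 0.13) and 1 of 11 for erythroid cells and platelets (Epb42, 0.23 ± 0.077). MHC class II presentation had 1 of 7 (Ctss, 0.44 ± 0.15), antioxidant defence 1 of 18 (Gpx1, 0.19 ± 0.060), hypoxia and glycolysis 1 of 17 (Pfkp, -0.26 ± 0.062), and T cell markers 2 of 14 (Cd4 0.30 ± 0.095, Cd3d 0.17 ± 0.050). These numbers were the same adjusted over the list alone, except 0 for erythroid cells and platelets and for antioxidant defence. In the MHC class II and alternatively activated macrophage lists, neither of which was called, the median was below 0 (-0.045 and -0.021) and the mean above it (0.12 and 0.13).

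Camera called 19 lists in water mice at 18 h. The p53 list had an adjusted p of 5.03e-19, which was 0.00376 with an estimated correlation, and it was the only list of the 19 to hold there. Limma on list means called 12 lists, which were p53 targets, ribosome biogenesis, integrated stress, DNA replication, mitosis, inflammatory, reactive oxygen, interferon gamma, endothelial, fibroblast, mast cell and immediate early genes (adjusted p = 0.0352 for the last). Of these 6 passed the exact permutation test as well (adjusted p = 0.042), namely p53 targets, ribosome biogenesis, integrated stress, DNA replication, inflammatory and reactive oxygen lists, while its adjusted p was 0.090 for interferon gamma and 0.064 for the other 5. Camera also called the NK cell and hypoxia lists, and their adjusted p with an estimated correlation was 0.46 and 0.64. With array medians subtracted the split of genes changed from 1233 higher and 1583 lower to 820 and 2280, and it turned to 99 and 25 with a minimum change of 1.5-fold and to 1265 and 1209 without water 0 h array 3.

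In antibiotic mice the same interval gave fewer calls. At 6 h 0 genes passed in limma, 0 in an ordinary linear model, and 2011 had an unadjusted p under 0.05, with a smallest adjusted p of 0.14. Mdm2 stood at 0.19 ± 0.076 and did not pass (adjusted p = 0.41). The gene with the smallest p among those higher was Scand1 (0.33 ± 0.067) and among those lower Wdr77 (-0.23 ± 0.044). The p53 list had 0 of 27 members past the threshold and 5 when adjusted over the list alone, and its camera adjusted p of 1.43e-06 became 0.40 with an estimated correlation. Its list mean was higher than at 0 h by 0.15 ± 0.048 (SE), and the lowest 6 h array (-0.146) lay above the highest 0 h array (-0.195). The exact permutation p was 0.0079, the smallest that 252 arrangements allow, and 0.25 adjusted over the 32 lists, and limma on list means did not call the list (adjusted p = 0.172). Without antibiotic 6 h arrays 1, 3 and 5 the number of genes was 17, 1 and 2.

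At 18 h in antibiotic mice 244 genes passed, 63 higher and 181 lower. The largest rises were Il6 (1.29 ± 0.31), Il1b (1.10 ± 0.24) and Trp53inp1 (0.94 ± 0.18). In the p53 list 7 of 27 members rose (11 adjusted over the list alone; adjusted p = 0.13 for the list with an estimated correlation), Btg2, an inhibitor of cell division, by 0.60 ± 0.11, and Mdm2 rose by 0.38 ± 0.076. Integrated stress genes fell in 5 of 15 cases (also 5 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation), with Chac1 at -1.29 ± 0.17 and Trib3 at -0.997 ± 0.15, and the transporters Slc6a9 (-0.98 ± 0.13) and Slc1a4 (-0.93 ± 0.097) fell with them. Ribosome biogenesis had 2 of 26 members lower, Polr1b (-0.27 ± 0.051) and Rrp12 (-0.26 ± 0.050), and 10 when adjusted over the list alone (adjusted p = 0.31 with an estimated correlation). Inflammatory genes had 2 of 24 higher, and 12 when adjusted over the list alone (adjusted p = 0.13 with an estimated correlation).

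List means tested by limma called the p53 (adjusted p = 0.00307), integrated stress (0.00112) and inflammatory (0.0117) lists in antibiotic mice at 18 h, and none of the 3 passed the exact permutation test (adjusted p = 0.13, 0.13 and 0.32). The number of genes was 46 when only these 2 groups were fitted, and 120, 146, 156, 133 and 94 without antibiotic 0 h arrays 2 and 5 and antibiotic 18 h arrays 2, 3 and 5. With array medians subtracted the split was 35 higher and 255 lower, and with a minimum change of 1.5-fold it turned to 11 and 7.

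**Figure D2:**
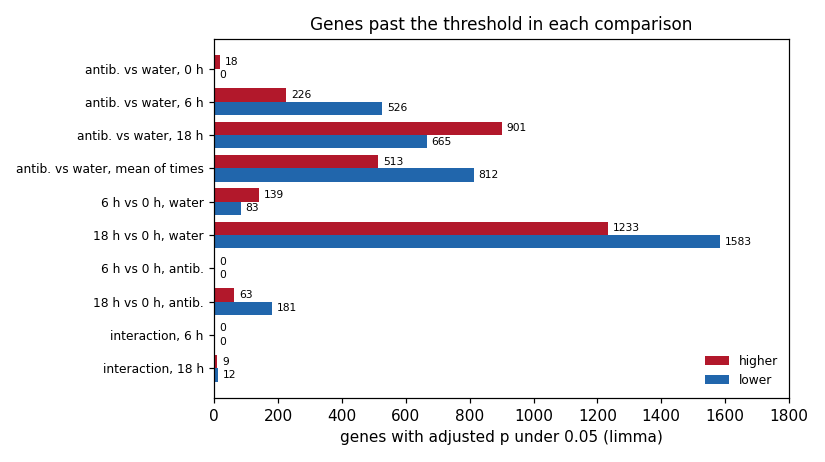
Number of genes that passed in each of the 10 comparisons (limma, adjusted p under 0.05, of 19938 genes), with higher genes in red and lower genes in blue. The 18 h response in water mice had the most calls (1233 higher and 1583 lower) and the 6 h response in antibiotic mice had 0.

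The response at 18 h in the 2 kinds of mice was compared without shared arrays. Of the 2816 genes called in water mice 88.3% changed in the same direction in antibiotic mice, with median changes of 0.23 and 0.088 in that direction, the first of which is raised by selecting on it. Of the 244 called in antibiotic mice 94.3% had the same direction in water mice. Both comparisons called 55 genes higher, where 3.9 would be shared by independent lists, 135 lower, where 14.4 would be, and 0 in opposite directions. The calls are not fully independent, because both comparisons use the same estimate of the spread of each gene, so the expected numbers may be too low.

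The interaction asks whether the change with time differed between antibiotic and water mice. At 18 h 21 genes passed, 9 with a more positive change in antibiotic mice and 12 with a more negative one. Among the first were the zinc transporter gene Slc39a10 (0.82 ± 0.12), Insig1, a regulator of sterol synthesis (0.64 ± 0.12), Hsph1 (0.47 ± 0.087) and the cell cycle kinase gene Wee1 (0.35 ± 0.066). Among the second were Sesn2 (-1.09 ± 0.22), a stress gene induced by p53 and by the integrated stress response, and Agrn (-0.60 ± 0.10). Sesn2 was the only p53 list member of 27 to pass, and 5 passed when adjusted over the list alone. Mean Sesn2 was 9.27 in water and 9.78 in antibiotic tumours at 0 h, and 10.1 and 9.53 at 18 h. Its interaction thus includes a gap at 0 h, and it cannot be assigned to p53 rather than to the integrated stress response. In 24 of the 27 members the change was more positive in water than in antibiotic mice.

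The p53 list mean changed by 0.48 in water and 0.21 in antibiotic mice at 18 h (SE 0.048 each), and the interaction was -0.27 ± 0.068. In limma on list means its adjusted p was 0.0168, and it was the only list of 32 called by that test. Camera called it with an adjusted p of 2.13e-11, and the adjusted p with an estimated correlation was 0.052. Hsph1 was the only heat shock gene of 9 to pass, and 4 passed when adjusted over the list alone. Tnf (-0.057 ± 0.090), Il1b (-0.028 ± 0.33), Cybb (-0.081 ± 0.32), Nos2 (0.28 ± 0.41), Ncf1 (-0.11 ± 0.17) and Sod2 (0.028 ± 0.052) did not pass.

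The count of 21 genes rested on single arrays. It was 6, 11 and 2 without water 0 h arrays 1, 2 and 4, 9, 13 and 11 without antibiotic 0 h arrays 2, 4 and 5, 3 and 72 without water 18 h arrays 3 and 5, and 2, 3 and 119 without antibiotic 18 h arrays 1, 4 and 5. The split of 9 higher and 12 lower became 65 and 56 after quantile normalisation and 5 and 3 with array medians subtracted. It also turned with trend and robust options (34 and 33), the interquartile range as covariate (78 and 62), a minimum change of 1.5-fold (3 and 2) and without 2 arrays of high keratinocyte lists (8 and 6). Higher calls outnumbered lower ones without water 0 h arrays 1, 2 and 3 (4 and 2, 7 and 4, 8 and 7), antibiotic 0 h arrays 2, 3, 4 and 5 (6 and 3, 10 and 8, 7 and 6, 8 and 3), water 18 h arrays 2 and 4 (8 and 6, 11 and 4) or antibiotic 18 h arrays 2 and 3 (8 and 7, 9 and 6), each left out alone. At 6 h 0 genes had an interaction that passed in limma, 0 in an ordinary linear model, and 1964 had an unadjusted p under 0.05, with a smallest adjusted p of 0.070 for Lgals12 (0.49 ± 0.085). One gene passed without water 0 h array 2 or 5, water 6 h array 5, or antibiotic 6 h array 1 or 2.

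**Figure D3:**
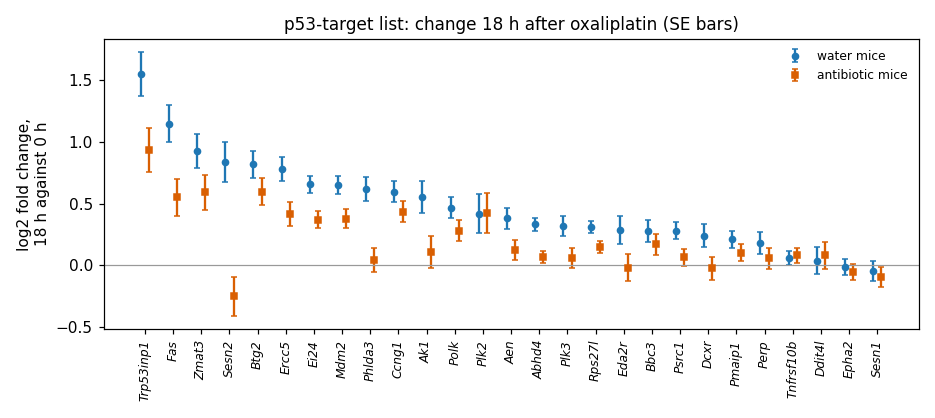
Change from 0 to 18 h after oxaliplatin of the 27 p53 list members as log2 fold change, in water (circles) and antibiotic (squares) mice; bars are SE. In 24 of 27 members the water value lies above the antibiotic value.

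At 0 h tumours of antibiotic mice had 18 genes higher and 0 lower than tumours of water mice. Some members of the integrated stress list were among them. Trib3, a pseudokinase induced by ATF4, was higher by 0.80 ± 0.15, Ddit3, a stress transcription factor, by 0.52 ± 0.086. Outside that list, the amino acid transporters Slc6a9 and Slc1a4 were higher by 0.65 ± 0.13 and 0.55 ± 0.097, and Pck2, a mitochondrial carboxykinase, by 0.54 ± 0.099. Cd69, a lymphocyte activation marker, was higher by 0.81 ± 0.16. In the integrated stress list 3 of 15 members passed, and 6 when adjusted over the list alone (adjusted p = 0.28 with an estimated correlation). Tnf (-0.072 ± 0.064), Il1b (0.057 ± 0.24), Cybb (-0.25 ± 0.23), Nos2 (-0.50 ± 0.29), Ncf1 (-0.20 ± 0.12) and Sod2 (0.020 ± 0.037) did not pass.

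At 0 h limma on list means called only integrated stress (adjusted p = 0.0264), which did not pass the exact permutation test (p = 0.0079, the smallest possible, and 0.25 adjusted over the 32 lists). The 18 genes became 7, 8 and 8 without water 0 h arrays 1, 4 and 5, and 32, 7 and 8 without antibiotic 0 h arrays 1, 2 and 4. The fit of only these groups called 4, and quantile normalisation gave 36 higher and 6 lower.

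At 6 h after oxaliplatin 226 genes were higher and 526 lower in antibiotic than in water tumours. The p53 list had 9 of 27 members lower (11 adjusted over the list alone) and 1 higher, with Trp53inp1 at -1.07 ± 0.18 and Fas at -0.83 ± 0.15, and Ddias was lower (-0.93 ± 0.17). With an estimated correlation the list's adjusted p was 0.32. Integrated stress genes were higher in 5 of 15 cases (8 adjusted over the list alone), Trib3 by 1.08 ± 0.15 and Chac1 by 0.98 ± 0.17, and the cystine transporter gene Slc7a11 was higher by 0.86 ± 0.21 (adjusted p = 0.14 for the integrated stress list with an estimated correlation). The largest positive values were hair and skin genes, Krt73 (1.55 ± 0.42) and Krt28 (1.54 ± 0.43). At that time 1 array of each group had a high keratinocyte list mean (2.14 in water, 1.94 in antibiotic mice). Yet the water 6 h group had the lowest means of the 6 groups for Krt73 (6.65, SD 0.57) and Krt28 (5.69, SD 0.52). In DNA repair 3 of 20 were lower, with Brca1 at -0.30 ± 0.067, and 1 was higher, Ercc1 (0.27 ± 0.050). There were 10 repair genes lower when adjusted over the list alone, and the adjusted p was 0.81 with an estimated correlation. Tnf (-0.0024 ± 0.064), Il1b (-0.36 ± 0.24), Cybb (-0.23 ± 0.23), Nos2 (-0.19 ± 0.29), Ncf1 (-0.13 ± 0.12) and Sod2 (-0.042 ± 0.037) did not pass.

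At 6 h the lists called by limma on list means were integrated stress (adjusted p = 3.34e-05) and p53 targets (adjusted p = 0.00139). The exact permutation test of list means gave p = 0.0079 for both, the smallest that 252 arrangements allow, and 0.13 adjusted over the 32 lists. In 6 of 100 regroupings of the arrays, the real one included, list means called 2 or more lists, and at most 9. A fit of these 2 groups alone called 9 genes. The number of genes was 397, 452, 333 and 358 without water 6 h arrays 1, 2, 4 and 5, and 192, 459 and 1420 without antibiotic 6 h arrays 3, 4 and 5. Quantile normalisation gave 385 higher and 469 lower, and the split turned to 154 higher and 47 lower without 4 arrays of the 6 h groups and to 27 and 18 with a minimum change of 1.5-fold.

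At 18 h 901 genes were higher and 665 lower in antibiotic tumours. The p53 list had 12 of 27 members lower and 0 higher, with Trp53inp1 at -0.81 ± 0.18 and Fas at -0.66 ± 0.15. Ribosome biogenesis was higher in 11 of 26 cases (Nop58 0.31 ± 0.058), DNA replication in 7 of 25 (Cdc6 0.28 ± 0.062), DNA repair in 3 of 20 (Chek1 0.33 ± 0.071), mitosis in 2 of 23 (Kif23 0.19 ± 0.048), heat shock in 3 of 9 (Hsph1 0.40 ± 0.061) and integrated stress in 4 of 15 (Chac1 0.70 ± 0.17), with 0 lower in each. Adjusted over the list alone the numbers were 21 lower for p53 targets and 20, 12, 8, 9, 4 and 6 higher for the lists in that order. In that order the adjusted p of the 6 lists was 0.19, 0.20, 0.37, 0.42, 0.19 and 0.19 with an estimated correlation. The angiomotin gene Amot was higher by 1.06 ± 0.15.

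Some phagocytosis, macrophage and phagocyte oxidase genes were lower in antibiotic tumours at 18 h. Phagocytosis genes were lower in 5 of 22 cases, including Cd36 (-0.73 ± 0.19) and the efferocytosis receptor Mertk (-0.57 ± 0.16), macrophage markers in 3 of 12, including Cd68 (-0.53 ± 0.10), and alternatively activated macrophage markers in 2 of 10, Chil3 (-1.21 ± 0.31) and Stab1 (-0.27 ± 0.070). The oxidase subunits Ncf4 (-0.29 ± 0.062) and Cyba (-0.28 ± 0.055) were the 2 of 12 reactive oxygen genes to pass, both lower. The differences in neutrophil (-0.072 ± 0.0997) and dendritic cell (-0.041 ± 0.059) list means were not called, and 0 of 17 and 0 of 9 members passed. Of 24 inflammatory genes 3 were lower (also 3 adjusted over the list alone), among them the chemokines Ccl2 (-0.60 ± 0.16) and Ccl7 (-0.53 ± 0.15). However, 9 members had positive differences, and limma on list means did not call the difference in list means of -0.078 ± 0.116 (adjusted p = 0.598). Also lower were 3 of 18 fibroblast and matrix genes (Mmp2 -0.58 ± 0.15) and 3 of 11 mast cell and eosinophil markers (Cma1 -0.34 ± 0.087). Adjusted over the list alone 12 phagocytosis, 5 macrophage, 4 alternatively activated macrophage, 5 reactive oxygen, 5 fibroblast and 3 mast cell genes were lower. With an estimated correlation the adjusted p was 0.27 for the phagocytosis list, 0.20 for both macrophage lists and the mast cell list, 0.35 for the fibroblast list and 0.043 for reactive oxygen. Tnf (-0.13 ± 0.064), Il1b (0.029 ± 0.24), Cybb (-0.33 ± 0.23), Nos2 (-0.21 ± 0.29), Ncf1 (-0.31 ± 0.12) and Sod2 (0.048 ± 0.037) did not pass.

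Of the 19 lists camera called at 18 h, p53 targets and reactive oxygen production held with an estimated correlation (adjusted p = 0.0163 and 0.043). Tested by list means, limma called 10 lists. Besides those it called ribosome biogenesis, integrated stress, DNA replication, macrophage, alternatively activated macrophage, mast cell and phagocytosis lists and T cell markers (0.27 as an adjusted p with an estimated correlation), where Cd4 (-0.31 ± 0.095) and Cd3d (-0.19 ± 0.050) were lower. The exact permutation test of list means did not pass for phagocytosis, mast cell and T cell (adjusted p = 0.12 each) and macrophage lists (0.077), and passed for the other 6 and for mitosis (0.036 each), which limma did not call. A fit of these 2 groups alone called 600 genes (296 higher and 304 lower), and 941, 926, 771 and 995 were called without water 18 h arrays 1 and 3 and antibiotic 18 h arrays 1 and 4, the last with 486 higher and 509 lower. With array medians subtracted 1458 were higher and 412 lower, and with a minimum change of 1.5-fold 10 and 25.

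**Figure D4:**
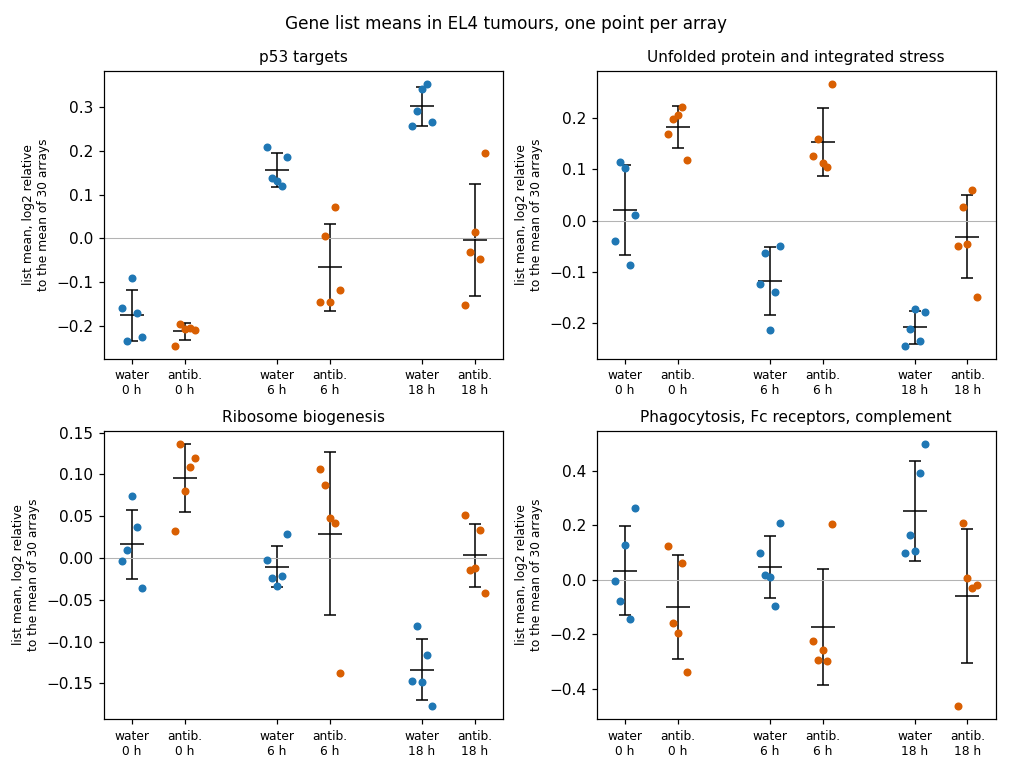
Means of 4 gene lists on each array, as log2 relative to the mean of the 30 arrays; blue points are water and orange points antibiotic tumours, horizontal marks are group means and bars are SD (n = 5). The p53 list rose from -0.18 to 0.30 between 0 and 18 h in water tumours, and from -0.21 to -0.0036 in antibiotic tumours.

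Averaged over the 3 times, 513 genes were higher and 812 lower in antibiotic tumours. Integrated stress genes were higher in 7 of 15 cases and lower in 0, led by Chac1 (0.82 ± 0.097) and Trib3 (0.77 ± 0.084), and Slc7a11 (0.92 ± 0.12), Slc6a9 (0.71 ± 0.077) and Slc1a4 (0.59 ± 0.056) were higher. Ribosome biogenesis was higher in 14 of 26 cases, with Pes1 at 0.18 ± 0.027 (adjusted p = 0.15 for the list with an estimated correlation). The p53 list was lower in 12 of 27 cases, phagocytosis genes in 7 of 22 (C3ar1 -0.38 ± 0.082), macrophage markers in 4 of 12 (Cd68 -0.39 ± 0.059, Ms4a7 -0.37 ± 0.073), alternatively activated macrophage markers in 2 of 10 (Folr2 -0.43 ± 0.11) and MHC class II genes in 2 of 7 (H2-Eb1 -0.33 ± 0.097), with 0 higher in each. The adjusted p was 0.20 for phagocytosis, 0.17 for both macrophage lists and 0.37 for MHC class II with an estimated correlation. When adjusted over the list alone 7 integrated stress genes were higher and 1 lower, 18 ribosome genes were higher, 1 p53 gene was higher, and 20 p53, 15 phagocytosis, 7 macrophage, 8 alternatively activated macrophage and 6 MHC class II genes were lower. Ncf4 was the only reactive oxygen gene to pass (-0.20 ± 0.036; 4 adjusted over the list alone; adjusted p = 0.073 for the list with an estimated correlation), and Ncf1 stood at -0.21 ± 0.071 (adjusted p = 0.074), Cybb at -0.27 ± 0.13 and Nos2 at -0.30 ± 0.17.

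In the average limma on list means called 8 lists. Of these p53 targets and integrated stress held in camera with an estimated correlation (adjusted p = 0.0131 for both). The others were reactive oxygen production, ribosome biogenesis, phagocytosis, both macrophage lists and MHC class II. Without antibiotic 6 h array 5 the number of genes was 2251. The split was 840 higher and 778 lower after quantile normalisation 813 and 477 with array medians subtracted and 8 and 3 with a minimum change of 1.5-fold.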

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

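The tests of compression and of a weaker response overall for the p53 list, and of the share of host cells for the macrophage list, were chosen after the results they measure had been seen, as was limma on list means. Skin and muscle covariates were planned, and the covariate for the spread of values was added later.

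Interaction terms were used to find responses that differed between water and antibiotic mice. At 18 h the median log2 difference of the p53 list was -0.25, and it was 0.15 for mitosis, 0.072 for DNA replication, 0.068 for DNA repair, 0.058 for ribosome biogenesis, 0.17 for heat shock, 0.17 for hypoxia and glycolysis, -0.14 for reactive oxygen production, -0.24 for interferon gamma and MHC class I, -0.14 for phagocytosis, -0.16 for mast cells and eosinophils, -0.19 for endothelial and -0.24 for fibroblast and matrix markers. At 6 h the medians were -0.097 for p53 targets, -0.063 for DNA replication, -0.16 for DNA repair, 0.12 for integrated stress, 0.19 for hypoxia and glycolysis, -0.15 for interferon gamma and MHC class I, 0.10 for T cell, -0.14 for endothelial, -0.23 for fibroblast and matrix and 0.57 for skeletal muscle markers. All 23 were called by camera with a preset correlation and 0 held with an estimated one. Without 4 arrays of the 6 h groups the medians at 6 h turned to -0.111 for skeletal muscle and -0.00038 for hypoxia and glycolysis.

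Single genes with an interaction at 18 h were Slc39a10 (0.82), Insig1 (0.64), Nmbr (0.61), Trmt10a (0.57), Hsph1 (0.47), Mfsd2a (0.42), Arhgap19 (0.40), Wee1 (0.35) and Vmn1r28 (0.30) on the positive side. On the negative side were Sesn2 (-1.09), Agrn (-0.60), Arl11 (-0.58), Pomt2 (-0.47), Tmco4 (-0.46), Baiap2 (-0.42), R3hcc1 (-0.41), Mrnip (-0.39), Dennd6b (-0.36), Afg1l (-0.35), Mks1 (-0.34) and Uqcc3 (-0.33).

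Between 0 and 18 h the p53 list rose less in antibiotic than in water mice (list mean interaction -0.269, SE 0.068). Camera's call of this interaction did not hold with an estimated correlation. With skin and muscle list means as covariates the interaction was -0.262 (SE 0.0682), and with the interquartile range of the array -0.272 (SE 0.0639). These values argue against the spread, and against skin and muscle as tracked by those lists, as the whole cause. Compressed changes on the antibiotic 18 h arrays cannot be told apart from a p53 effect by the first test, in which the antibiotic to water ratio of the integrated stress list exceeded that of the p53 list by 0.5 (SE 0.28). A further test, added once that result was known, found an interquartile range ratio of antibiotic to water 18 h arrays of 1 (SE 0.02), which argues against compressed values over the whole array but leaves compressed changes open. A weaker response of all responding genes stays open too, because the slope over genes outside the list was 0.555 (jackknife SE 0.31) beside 0.437 (SE 0.11) for the p53 list. The antibiotics may therefore have weakened the whole change with time after the drug or that of p53 targets.

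The integrated stress list was higher in antibiotic than in water mice over the 3 times (0.204, SE 0.0249). It was 0.205 (SE 0.0237) with skin and muscle covariates and 0.209 (SE 0.0249) with the interquartile range as covariate. These values argue against the spread, and against skin and muscle as tracked by the 2 lists, as the cause. The group means of Krt73 and Krt28 at 6 h did not follow the keratinocyte list, so skin content that this list misses stays open. The antibiotic treatment stays open as the biological difference the design names. No mechanism was tested, and the design cannot say whether lost bacteria or the antibiotics themselves lie behind it.

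The macrophage list was lower in antibiotic than in water mice over the 3 times (-0.232, SE 0.0642). Camera's call of this list did not hold with an estimated correlation. With skin and muscle covariates the list mean difference was -0.236 (SE 0.0417) and with the interquartile range -0.216 (SE 0.0647). A smaller share of all host cells would lower endothelial and fibroblast markers alike. Relative to these the macrophage list was still lower over the 3 times (-0.138, SE 0.0544), which argues only weakly against that share as the whole cause of the average. The gap was widest at 0 h, where list means differed by -0.208 (macrophage), 0.0556 (endothelial) and 0.0248 (fibroblast). They differed by -0.182, -0.103 and -0.189 at 6 h and by -0.305, -0.111 and -0.235 at 18 h. The macrophage difference at 0 h had an exact permutation p of 0.12 (0.59 adjusted over the 32 lists). Water 0 h array 5 had the highest macrophage list mean of its group (0.399), with endothelial and fibroblast means of -0.115 and -0.049. How far the gap rests on that array was not tested. A smaller share of host cells stays open at 6 and 18 h, where the gap alone was not tested. The brightest member of the macrophage list, Lyz2 (mean 11.5 on the log2 scale, chosen after its values were seen), stood at -0.22 ± 0.076 and did not pass. Fewer macrophages or lower expression per cell may both underlie the lower list, and no test here separates them.

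The number of genes exceeded that of every other split tried in 8 of the 10 comparisons. The splits mix groups that may differ, which can widen the error and lower their counts, so the margin may be overstated. With 1 array left out, the real count fell as low as 192 for antibiotics against water at 6 h and 2 for the interaction at 18 h. Both are below the highest other splits (529 and 3), which used all arrays. In 100 splits of the arrays, 1 (the real one) gave as many genes for antibiotics against water at 0 h (18, highest other 0), at 6 h (752, 529), at 18 h (1566, 409) and averaged (1325, 1), for water mice at 6 h (222, 1) and 18 h (2816, 476), for antibiotic mice at 18 h (244, 83) and for the interaction at 18 h (21, 3). For antibiotic mice at 6 h and the interaction at 6 h the real count was 0. All 100 splits give as many whatever their values, so the splits cannot decide about chance there. The highest others were 429 and 1. The 429 may reflect a structure among the 10 arrays of antibiotic mice at 0 and 6 h, which was not identified. Single splits reached similar counts in other comparisons (529, 409 and 476). Chance was not excluded for any count of lists called by camera: in the order of the comparisons used in the methods, 23, 64, 14, 31, 16, 8, 68, 63, 54 and 38 of 100 splits called as many lists (13, 10, 19, 14, 13, 19, 10, 9, 10 and 13, with highest others of 20, 23, 22, 23, 17, 20, 26, 23, 23 and 24). Limma on list means called 1, 2, 10, 8, 3, 12, 0, 3, 0 and 1 lists in that order, with highest others of 1, 9, 8, 1, 1, 5, 5, 6, 6 and 1, and 3, 6, 1, 1, 1, 1, 100, 4, 100 and 3 of 100 splits called as many. Chance was therefore not excluded for this count for antibiotics against water at 6 h, and for the 2 comparisons with 0 lists the splits cannot decide. In the others few splits called as many, but this test was chosen after the data were seen and 10 comparisons were tried. At 0 h and for the interaction at 18 h the highest other equalled the real count of 1. For antibiotic mice at 18 h it exceeded the real count (6 against 3). The limit of mixed groups holds for these counts too.

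Single arrays stood apart from the other 4 of their group in 19 of 204 cases, where about 10.2 are expected by chance. Antibiotic 6 h array 5 was high in the list means of hypoxia and glycolysis (0.815), type I interferon (0.57), phagocytosis (0.205), circadian clock (0.29) and glucocorticoid response (0.34) and low in ribosome biogenesis (-0.138). Antibiotic 0 h array 1 was low in p53 targets (-0.245), DNA repair (-0.106) and T cell markers (-0.0694), and array 4 of that group was high in interferon gamma and MHC class I (0.24). Antibiotic 18 h array 1 was low in reactive oxygen production (-0.205), endothelial markers (-0.203) and glucocorticoid response (-0.385) and high in keratinocyte markers (0.435). Water 6 h array 1 was high in keratinocyte markers (2.14), with a median correlation with the other arrays of 0.992, and water 6 h array 2 was low in adipocyte markers (-0.181). Water 0 h array 3 was high in endothelial markers (0.109), and antibiotic 6 h array 3 had a narrow interquartile range of 2.79.

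Rows without a single gene symbol were left out of the counts of genes and fitted on their own. Of 7078 such rows 497 passed between 0 and 18 h in water mice, 139 higher and 358 lower, and 20 at 6 h. For antibiotics against water 1, 41, 105 and 81 passed at 0, 6 and 18 h and averaged, in antibiotic mice 0 and 18 at 6 and 18 h, and for the interaction 0 and 3.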

How the results depend on the processing

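The alternatives with the interquartile range as covariate, and those leaving out 2 or 4 arrays that stood apart, were chosen after the data were seen. The cause of each change was not tested, except that leaving out genes or arrays changes what is tested. Counts are of genes that passed; the counts as first analysed were 18, 752, 1566 and 1325 for antibiotics against water at 0, 6 and 18 h and averaged, 222 and 2816 for water mice at 6 and 18 h, 0 and 244 for antibiotic mice, and 0 and 21 for the interaction. Quantile normalisation gave 42 at 0 h, 3 and 369 in antibiotic mice and 1 and 121 for the interaction, and subtracting array medians gave 30 at 0 h, 470 at 6 h and 8 for the interaction at 18 h. Leaving out the dimmest 40% of genes gave 34 at 0 h, 354 in water mice at 6 h, 406 in antibiotic mice at 18 h and 77 for the interaction at 18 h. Fits of only the groups compared gave 4, 9 and 600 for antibiotics against water at the 3 times, 46 in antibiotic mice at 18 h and 12 for the interaction at 18 h; this setting does not apply to the average, which uses all arrays. Trend and robust options gave 2 in antibiotic mice at 6 h and 67 for the interaction at 18 h, and an ordinary linear model gave 34 for the latter. Array weights gave 126 at 0 h, 1266 at 6 h, 2251 averaged, 815 in water mice at 6 h, 1 and 569 in antibiotic mice and 1 and 121 for the interaction. Skin and muscle covariates gave 1266 for antibiotics against water at 6 h and 4 in antibiotic mice at 6 h. A change of at least 1.5-fold as well left 3, 45, 35 and 11 for antibiotics against water, 24 and 124 in water mice, 18 in antibiotic mice at 18 h and 5 for the interaction at 18 h, so most calls were of small size. The interquartile range as covariate gave 40, 307 and 2390 for antibiotics against water, 336 in water mice at 6 h, 610 in antibiotic mice at 18 h and 140 for the interaction at 18 h. Without the 2 arrays with high keratinocyte lists 294 genes passed for antibiotics against water at 6 h, 114 in water mice at 6 h and 13 in antibiotic mice at 6 h. Without the 2 arrays of narrowest spread 216 passed for antibiotics against water at 6 h. Without 4 arrays of the 6 h groups 61 and 201 passed for antibiotics against water at 0 and 6 h, 34 in antibiotic mice at 6 h and 39 for the interaction at 18 h. Leaving out each array in turn gave 7 to 32, 192 to 1420, 771 to 1686 and 1009 to 2251 for antibiotics against water, 119 to 191 and 2089 to 2732 in water mice, 0 to 17 and 94 to 346 in antibiotic mice, and 0 to 1 and 2 to 119 for the interaction. The 18 h response in water mice stayed within 1.5 times of its count under all alternatives except the minimum change.

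Lists reversed in few cases. The median of the hypoxia list in water mice at 6 h was 0.0543 with skin and muscle covariates, and that of the type I interferon list for antibiotics against water at 6 h was -0.01 with the interquartile range as covariate, where the list's test turned upward without passing (adjusted p = 0.94). Without 4 arrays of the 6 h groups the muscle list for antibiotics against water at 6 h was -0.319 and its interaction -0.111, DNA replication in antibiotic mice at 6 h was -0.0033, where only the test turned, and the hypoxia interaction -0.00038. Leaving out each array in turn, the muscle list for antibiotics against water at 6 h ranged from -0.0113, without antibiotic 6 h array 5, to 0.564. Of 130 list calls by camera 6 held with an estimated correlation, 42 in fry and 40 in limma on list means. Named genes lost significance in 71 cases in fits of only the groups compared (205 stayed on their side of the threshold), and in 36 each without the 2 keratinocyte or the 2 narrow arrays, 28 without 4 arrays, 26 with medians subtracted, 25 in the ordinary linear model, 15 with trend and robust options, 11 with the interquartile range and 7 or 8 with array weights, covariates or quantile normalisation. In leave-one-out 524 lost it, 16 gained it and 4070 did neither. List tests under the ordinary linear model were not run, since camera moderates the variance. No paired analysis was possible because the sample numbers run through the series and pair no samples. Subtracting medians or quantile normalisation moved the median of all genes by less than 0.1 on the log2 scale. Signal over background is not given by the deposited values, so genes near background could not be marked.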

Other observations

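The comparison of the antibiotic difference at separate times was chosen after the data were seen.

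Circadian clock genes differed in a few members. Ciart, a repressor of the clock, was higher in antibiotic than in water tumours by 0.54 ± 0.11 (SE) at 0 h, 0.52 ± 0.11 at 6 h and 0.48 ± 0.11 at 18 h on the log2 scale, and it fell between 0 and 18 h in water (-0.60 ± 0.11) and in antibiotic mice (-0.66 ± 0.11). Nr1d1, a clock repressor, was lower at 18 h in antibiotic (-0.32 ± 0.061) and in water mice (-0.24 ± 0.061). Tef was higher in water mice (0.30 ± 0.056) and did not pass in antibiotic mice (0.057 ± 0.056), and its interaction did not pass either (-0.24 ± 0.079). Of 16 clock genes 5 passed in water mice at 18 h, 1 higher and 4 lower, and limma on list means did not call the list (adjusted p = 0.11). That test cannot decide here, because the list holds genes that cycle in opposite phase and can cancel in a mean. The plan was to read this list from its members and from a form of fry that ignores direction, whose result is not given here. Times of day are not given in the sources used here.

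Glucocorticoid response genes passed in 2 of 10 cases at 18 h in each kind of mouse, in both lower. Fkbp5, a glucocorticoid-induced chaperone partner, was at -0.25 ± 0.047 in water and -0.20 ± 0.047 in antibiotic mice, and Tsc22d3 at -0.46 ± 0.086 in antibiotic mice and, without passing, at -0.15 ± 0.086 in water mice. The list was not called by limma on list means (adjusted p = 0.85 and 0.48), and camera's call in antibiotic mice had an adjusted p of 0.43 with an estimated correlation.

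The 18 genes that were higher in antibiotic tumours at 0 h were compared at the later times. All 18 had the same sign at 6 h, where 15 were called higher against 0.204 expected for independent lists, and all 18 at 18 h, where 7 were called against 0.813 expected. These comparisons share no arrays, but they use the same estimate of the spread of each gene. The expected numbers here may therefore be too low. Of the 752 genes called at 6 h 59% had the same sign at 18 h. Both times called 45 genes higher, against 10.2 expected for independent lists, 97 lower, against 17.5 expected, and 32 in opposite directions.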
